A study of Mus musculus with 6 samples.

How the data were processed

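Whole mouse ovaries taken at 1 day post partum (dpp) were profiled by RNA sequencing of total RNA. The labels put 3 samples in a wild-type (WT) group and 3 in a group in which Bcas2, a subunit of the PRP19/CDC5L splicing complex, was deleted in oocytes (Bcas2 cKO, conditional knockout). A description label of the samples speaks of granulosa cells, while the titles, the tissue and the study design give ovary, so the values were read as those of whole ovaries. Groups and replicate numbers were taken from the sample titles, and each column of values was matched to its sample by the sample descriptions. Which driver and which exons were used for the deletion, and whether each sample came from a separate animal or from pooled ovaries, is not given in the sources used here, so p-values measure the spread between these samples, which may in part be technical.

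The authors deposited FPKM values, that is fragments scaled to gene length and library size, for 47122 gene models with a gene length, a symbol, a biotype and coordinates. HISAT2 2.0.5 and the builds mm10 and GRCm39 are named per the submitters' processing notes, and the coordinates in the deposited table use GRCm39 sequence accessions. The counting tool, the annotation release, the strand setting and any filter are not given in the sources used here. Reads from overlapping genes on opposite strands, from gene families and from processed pseudogenes may therefore be shared between rows. Of the deposited gene models, 789 had no symbol, and the 508 of them that passed the filter on low values were kept in the tests.

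The deposited FPKM multiplied by the gene length and divided by a single step per library gave whole numbers. Values with the highest read numbers were left out of this check. Of the other values above 0, 100% lay within 0.05 of a whole read in each library. The reads recovered in this way summed to 18121659, 17252045 and 19565275 in WT replicates 1, 2 and 3, and to 16887623, 16800421 and 18382568 in cKO replicates 1, 2 and 3. The library size implied by the step was 0.962 to 1.03 times that sum, so the depositors' library sizes were not the plain totals of these reads. A single read on a gene of 1 kb was worth 0.0512 to 0.0594 FPKM, and genes near 1 FPKM rest on few reads when they are short: 222 of the tested genes had fewer than 10 recovered reads in every library. Replicates of each group differed by more than sampling noise in a chi-square comparison of recovered reads, with 13.3 to 66.6 per degree of freedom over the 6 pairs, so no pair looked like a library deposited more than once. That spread does not show whether the libraries are separate biological samples.

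Values were tested as log2(FPKM + 1) without further scaling, so fold changes are on that scale and understate the change of genes with low values. Genes with an FPKM of at least 1 in at least 3 of the 6 samples were kept, which left 14589 genes, 12394 of them protein-coding. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend in the prior spread, two-sided), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Bcas2 was treated as a single planned test of the labels, with an exact two-sided permutation test of its 6 values beside it. With 3 samples against 3, such a permutation test cannot give a p below 0.1.

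Gene lists for 22 cell types, pathways and handling effects were tested with camera in limma, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists, and 20 of them had at least 3 tested members. Camera with an estimated correlation and fry were run beside it. Older symbols were matched through the synonyms of a RefSeq gene table for GRCm38.p6, by gene identifier, and the mitochondrial list was taken as the 13 protein-coding genes of the mitochondrial genome. Symbols of 4 list entries were not matched. A list mean is the mean log2(FPKM + 1) of its tested members in a library. The number of introns per gene came from GENCODE M21, a GRCm38 annotation used only through gene symbols, and was found for 97.4% of the tested protein-coding genes.

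The samples, the test, the lists, the alternative settings and the rule for naming genes were set before the data were examined. The rule took Bcas2, up to 12 genes with the largest rise and up to 12 with the largest fall among those past the threshold with non-overlapping groups, a mean FPKM of at least 2 in the higher group and an established symbol, the 4 tested members of each list with the smallest p, and 15 reference genes: Ddx4, Dazl, Sycp3, Figla, Nobox, Gdf9, Zp3, Kit, Foxl2, Amh, Kitl, Cdkn1a, Trp63, Prpf19 and Cdc5l. Other genes are named only with the statement that they were chosen after their values were seen. The alternative settings were a pseudocount of 0.1 or 0.5, no filter on low values, a filter at 5 FPKM, rescaling to TPM, median-of-ratios scaling, quantile normalization, a replicate block, a prior spread without a trend, array weights, a 2-fold minimum, protein-coding genes only, and leaving out each replicate in turn. A further 3 were chosen after seeing the data: limma-voom on the recovered reads, leaving out WT replicate 1 and cKO replicate 2 together, and removing each library's trend with gene length.

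The test was checked on simulated reads with 200 changed genes, and again after 200 genes were multiplied by a known fold in the real cKO libraries. In the simulated comparison of Bcas2 cKO with WT, 89.5% of 2-fold and 98.5% of 4-fold changes were recovered at the threshold. In the real libraries, 46.5% of 2-fold and 84.0% of 4-fold changes were recovered. Unchanged genes called at 2-fold and 4-fold numbered 16 and 12 in the simulated reads, and 5 and 8 in the real libraries. The simulated reads gave every gene the same dispersion between libraries. Changing 200 genes at once makes the adjusted threshold easier to reach. These rates therefore do not apply where few genes change.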

Results

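Ovaries of newborn mice at 1 dpp, the age at which oocytes are completing meiotic prophase and are being enclosed in primordial follicles, were compared between 3 WT samples and 3 samples with Bcas2 deleted in oocytes. The comparison asks how gene expression in the ovary differs when oocytes lack this splicing factor. The recovered reads of a library numbered between 16800421 and 19565275.

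Bcas2 itself was measured first. It lies on chromosome 3 from position 103078971 to 103086479 on the plus strand (GRCm39, gene identifier 68183), and no other gene of the table overlaps it. Its level was 54.5, 37.5 and 35.7 FPKM in the WT ovaries and 18.9, 21.9 and 18.3 FPKM in the cKO ovaries. The group means were 42.6 ± 10.4 FPKM in WT and 19.7 ± 1.92 FPKM in cKO (SD, n = 3 each), a ratio of 0.463. All 3 cKO values lay below all 3 WT values, with a log2 fold change of −1.05 (SE 0.17, 95% interval −1.46 to −0.64). As a single planned test, limma gave p = 0.000502, and the exact permutation test gave p = 0.1, the smallest it allows with 3 against 3. Adjusted over all 14589 genes, the limma p was 0.955. The values are totals over the gene, and cells other than oocytes are also in the sample, so the level left in oocytes was not measured. The 14 other tested genes within 1 Mb on either side had log2 fold changes between −0.59 and 0.17, and none of them had an unadjusted p under 0.05. Among these neighbours Trim33, chosen after its values were seen, was at 15.7 ± 0.889 FPKM in WT and 14.5 ± 0.668 FPKM in cKO (SD, n = 3 each).

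**Figure D1:**
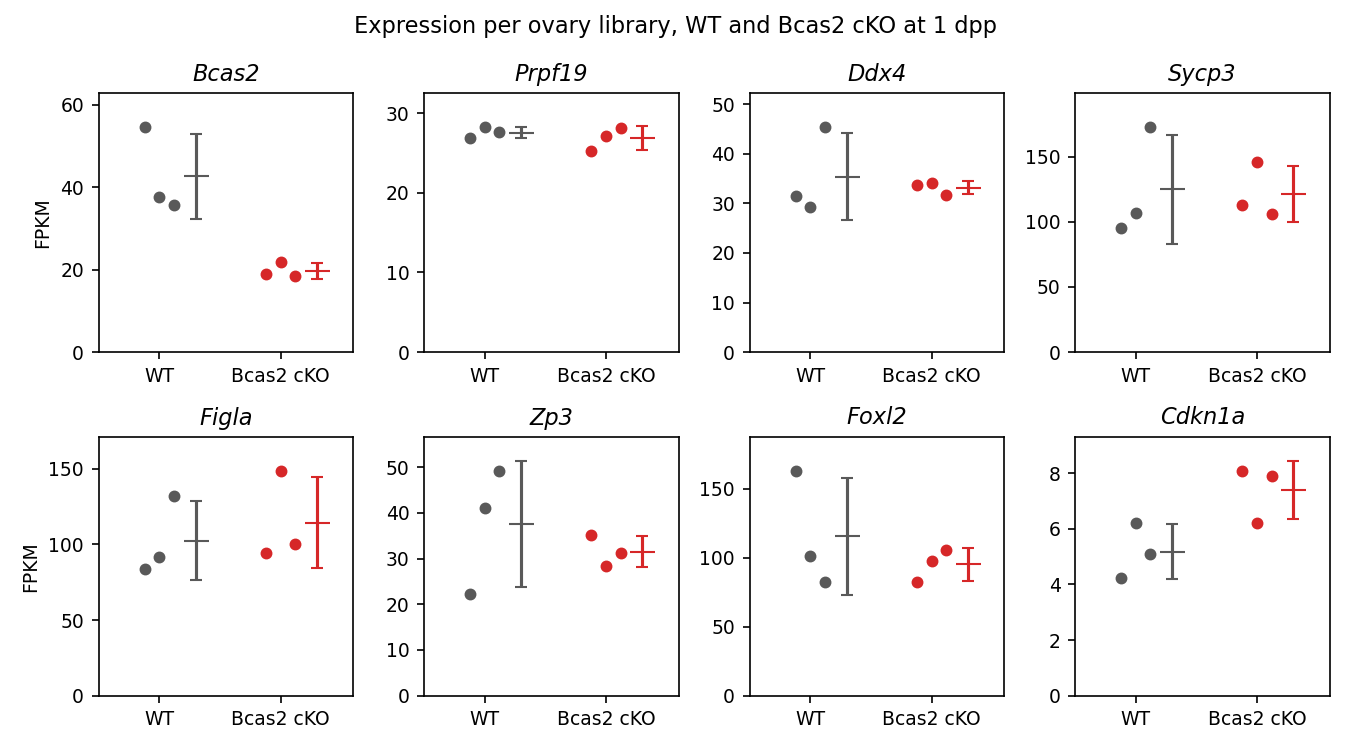
FPKM of 8 genes in the 3 WT (grey) and 3 Bcas2 cKO (red) ovary libraries, with points for libraries in order of replicate and a bar for the mean ± SD (n = 3 each). Bcas2 lies between 35.7 and 54.5 FPKM in WT and between 18.3 and 21.9 FPKM in cKO, while the values of the other 7 genes overlap between groups.

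Across all genes, 0 rose and 0 fell at an adjusted p under 0.05 in limma, and the smallest adjusted p was 0.484. At an unadjusted p under 0.05 there were 443 genes, 276 higher and 167 lower in cKO. They made up 3.04% of those tested and were fewer than the 729 expected by chance. Other splits of the samples into 3 and 3 gave between 228 and 1689 such genes. For the real groups, the count of 443 became 1056 without WT replicate 3, 702 without cKO replicate 3, 293 without cKO replicate 1, 253 without cKO replicate 2 and 1990 with array weights. The groups did not overlap for 1149 genes, or 7.88%, where chance gives 10%. Limma-voom on the recovered reads, an alternative chosen after seeing the data, also called 0 genes, with 490 at an unadjusted p under 0.05. The median 95% interval reached 0.35 on the log2 scale to either side of the estimate. The smallest p-values, for genes chosen after their values were seen, belonged to the microRNA genes Mir6999 and Mir7669, both listed at 0 in all 3 cKO libraries and resting on at most 4 reads in any WT library. Both reached 1 FPKM in WT libraries only, so their higher level in WT also decided that they were tested. Without cKO replicate 2 the count became 1, the processed pseudogene Pcna-ps2, and with array weights it became 1, Mir6999.

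**Figure D2:**
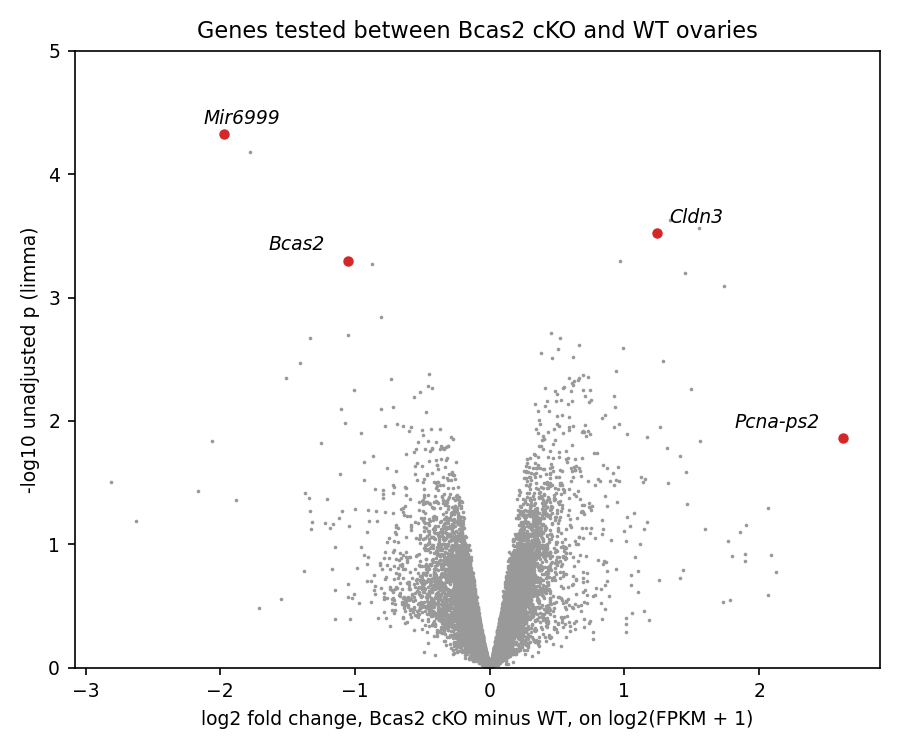
Log2 fold change on log2(FPKM + 1), Bcas2 cKO minus WT, on the x axis against −log10 of the unadjusted limma p on the y axis, with a point for each of the 14589 genes tested. Bcas2, at a log2 fold change of −1.05, and 3 genes chosen after their values were seen are marked in red; 0 genes passed the adjusted threshold.

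Levels of the oocyte genes named here overlapped between the groups. Of the 45 members of the oocyte growth and zona list in the table, 32 passed the filter, and of these 0 rose, 0 fell and 32 did not pass the test, also when adjusted over the list alone, and their median log2 fold change was 0.04. Figla, a transcription factor needed for primordial follicle formation, stood at 102.4 ± 26.1 FPKM in WT and 114.5 ± 29.8 FPKM in cKO. Nobox, another oocyte transcription factor, stood at 63.9 ± 15.7 and 67.3 ± 1.73 FPKM, and Zp3, a zona pellucida glycoprotein, at 37.6 ± 13.8 and 31.6 ± 3.41 FPKM (SD, n = 3 each). Gdf9, an oocyte growth factor, was at 9.88 ± 3.05 and 7.85 ± 1.16 FPKM, and Dppa3, a maternal-effect gene, at 402.8 ± 86.9 and 495.4 ± 77.1 FPKM. The list mean was 4.56 ± 0.38 in WT and 4.58 ± 0.03 in cKO. Camera gave an adjusted p of 0.670. That result turned with single WT libraries: the list was called lower in cKO without WT replicate 1 (adjusted p = 0.000298, median −0.14) and higher without WT replicate 3 (adjusted p = 0.000577, median 0.22), with adjusted p = 0.767 and 0.468 under an estimated correlation.

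Germ cell identity and piRNA pathway genes gave a similar picture. Among 25 tested members 0 rose, 0 fell and 25 did not pass, with 0 passing when adjusted over the list alone and a median log2 fold change of 0.04. Ddx4, the germ cell RNA helicase, was at 35.4 ± 8.69 FPKM in WT and 33.2 ± 1.29 FPKM in cKO, and Dazl, a germ cell RNA-binding protein, at 102.9 ± 27.0 and 116.8 ± 13.8 FPKM (SD, n = 3 each). Dnd1, an RNA-binding protein of germ cells, was at 4.99 ± 1.02 and 8.01 ± 0.736 FPKM, with non-overlapping groups and an adjusted p of 0.955 in limma. Camera gave an adjusted p of 0.1003 for the list. Without WT replicate 3 the list was called higher in cKO (adjusted p = 6.98e-08, median 0.21, and 0.468 with an estimated correlation). The receptor gene Kit, expressed by oocytes, was at 157.9 ± 31.8 FPKM in WT and 141.2 ± 15.4 FPKM in cKO, and Trp63, which encodes the p53 relative that guards oocyte DNA integrity, at 14.8 ± 2.31 and 12.9 ± 1.62 FPKM.

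Meiotic prophase genes were slightly higher in the list mean, with overlapping groups. That mean was 3.21 ± 0.26 in WT and 3.35 ± 0.16 in cKO (SD, n = 3 each, exact permutation p = 0.5). Of 46 tested members 0 rose, 0 fell and 46 did not pass, with 0 passing when adjusted over the list alone. The median log2 fold change was 0.12, and 34 of the 46 had a higher mean in cKO. Camera with the preset correlation called the list up (adjusted p = 0.00645), but with an estimated correlation the adjusted p = 0.847. Sycp3, an axial element protein of the synaptonemal complex, was at 124.9 ± 41.7 FPKM in WT and 121.6 ± 21.6 FPKM in cKO. Hormad1, a meiotic chromosome axis protein, was at 27.7 ± 16.5 and 41.3 ± 4.74 FPKM, and Spo11, which makes meiotic double-strand breaks, at 1.91 ± 0.580 and 2.998 ± 0.665 FPKM (SD, n = 3 each). Psmc3ip, a cofactor of meiotic strand exchange, was at 4.67 ± 0.496 and 5.97 ± 0.571 FPKM. The call was lost without WT replicate 1 (adjusted p = 0.461, median 0.05), without WT replicate 2 (0.405, median 0.03) or without cKO replicate 2 (0.372, median 0.03). The median was 0.28 without WT replicate 3 and 0.06 after rescaling to TPM, with the call kept.

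Splicing genes of 2 lists, other than Bcas2, did not pass over all genes or adjusted over the list alone. In the PRP19 complex list, 19 members were tested, 0 rose, 0 fell and 19 did not pass over all genes, while 1, Bcas2, passed when adjusted over the list alone. Its partners Prpf19, a ubiquitin ligase, and Cdc5l, a scaffold of the complex, were at 27.5 ± 0.701 and 29.0 ± 4.46 FPKM in WT and at 26.9 ± 1.48 and 30.0 ± 0.599 FPKM in cKO (SD, n = 3 each). The median log2 fold change of the list was 0.06, with an adjusted camera p of 0.414. Of 57 core spliceosome and SR protein genes 0 rose, 0 fell and 57 did not pass, with 0 passing when adjusted over the list alone, a median log2 fold change of 0.03 and an adjusted camera p of 0.587. Prpf8, the core protein of the U5 particle, was at 70.2 ± 7.48 FPKM in WT and 57.4 ± 6.93 FPKM in cKO, and Srrm1, a splicing coactivator, at 42.5 ± 5.35 and 35.2 ± 0.396 FPKM, with non-overlapping groups and an adjusted p of 0.955 in limma (SD, n = 3 each). Gene totals do not show how transcripts were spliced, so exon usage was not measured.

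The p53 target list and the DNA repair list held no member that passed, over all genes or adjusted over the list alone. Of 30 tested p53 targets 0 rose, 0 fell and 30 did not pass, with a median log2 fold change of −0.0037 against a direction of up in camera (adjusted p = 0.670). Cdkn1a, a cell cycle inhibitor induced by p53, was at 5.18 ± 0.986 FPKM in WT and 7.39 ± 1.05 FPKM in cKO, and Bax, a pore-forming protein of cell death, at 48.2 ± 6.66 and 63.3 ± 16.5 FPKM (SD, n = 3 each). Their limma adjusted p was 0.955 each. Of 38 DNA repair and checkpoint genes 0 rose, 0 fell and 38 did not pass, with a median of −0.06 and an adjusted camera p of 0.169. Atr, a checkpoint kinase, was at 22.05 ± 4.74 FPKM in WT and 17.3 ± 0.710 FPKM in cKO, and Rad52 at 3.66 ± 0.245 and 4.60 ± 0.346 FPKM. Without WT replicate 1 the DNA repair list was called lower in cKO (adjusted p = 1.97e-05, median −0.12, and 0.415 with an estimated correlation).

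Pregranulosa genes, expressed by the somatic cells that surround the oocytes, went both ways, with log2 fold changes from −0.68 to 0.69. Of 30 tested members 0 rose, 0 fell and 30 did not pass, with 0 passing when adjusted over the list alone, a median log2 fold change of −0.06 and an adjusted camera p of 0.510. Foxl2, a granulosa cell transcription factor, was at 115.6 ± 42.3 FPKM in WT and 95.3 ± 11.9 FPKM in cKO, and Kitl, the ligand of Kit, at 76.1 ± 21.98 and 69.5 ± 15.5 FPKM. Rspo1, a Wnt activator of the fetal ovary, was at 61.2 ± 8.84 and 78.2 ± 2.59 FPKM, with non-overlapping groups and an adjusted p of 0.955 in limma (SD, n = 3 each). Amh stayed below the filter. Without WT replicate 3 the list was called lower in cKO (adjusted p = 0.00939, median −0.18, and 0.468 with an estimated correlation).

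The libraries differed in tissue genes within groups. WT replicate 1 lay far from the others on the first principal component, which held 46.3% of the variance. Its endothelial list mean lay 1.28 above the mean of the 6 libraries on the log2 scale, its pericyte and smooth muscle mean 1.24 above and its stroma mean 0.71 above, while its surface epithelium mean was at −0.71. Pecam1, an endothelial adhesion protein, was at 24.5 FPKM in that library and between 6.62 and 8.45 FPKM in the other 5. Among the tested members of these 4 lists 0 rose and 0 fell, and 0 passed when adjusted over the list alone. Over all libraries, camera with the preset correlation called endothelial genes (15 tested, median log2 fold change −0.45, adjusted p = 0.00829), pericyte and muscle genes (11 tested, −0.44, adjusted p = 0.0260) and stroma and theca genes (18 tested, −0.32, adjusted p = 0.0242) lower in cKO, and surface epithelium genes (15 tested, 0.18, adjusted p = 0.0454) higher. With an estimated correlation each of the 4 had an adjusted p = 0.847. Without WT replicate 1, endothelial genes were called higher in cKO instead (adjusted p = 0.0137, median 0.10, and 0.767 with an estimated correlation), and the signs of pericyte (adjusted p = 0.0611, median 0.12), stroma (0.951, 0.02) and surface epithelium genes (0.0697, −0.08) turned. Without WT replicate 3 the medians were −0.77 for endothelial, −0.79 for pericyte and −0.62 for stroma genes. Without cKO replicate 3 all 4 calls were lost (endothelial adjusted p = 0.0754, median −0.36; pericyte 0.116, −0.48; stroma 0.0724, −0.41; surface epithelium 0.418, 0.10). Without cKO replicate 2 the pericyte (0.140, median −0.27) and stroma calls (0.132, −0.26) were lost, and without cKO replicate 1 the surface epithelium call (0.0527, median 0.19). The surface epithelium median was 0.46 without WT replicate 2 and 0.28 without cKO replicate 2. Rescaling to TPM ended the stroma, endothelial and pericyte calls (adjusted p = 0.102, 0.0710 and 0.132), no filter ended the stroma and surface epithelium calls (0.0772 and 0.130), quantile normalization the surface epithelium call (0.0899), and voom the pericyte and surface epithelium calls (0.0555 each).

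Blood and handling genes also differed between libraries of the same group. In cKO replicate 2 the beta-globin gene Hbb-bt was at 1690 FPKM, against 27.0 to 119.9 FPKM in the other 5. The erythroid list (11 tested, median log2 fold change 1.80) was called higher in cKO (adjusted p = 0.000426, and 0.847 with an estimated correlation). Its median was 0.33 without cKO replicate 2 (adjusted p = 0.0340) and 2.71 without cKO replicate 1. Immediate-early and heat-shock genes (18 tested, median −0.65) were called lower in cKO (adjusted p = 0.000619, and 0.847 with an estimated correlation). Egr1, an early response transcription factor, was at 66.03, 171.4 and 13.1 FPKM in WT and at 8.60, 8.66 and 18.5 FPKM in cKO, and without WT replicate 2 the call was lost (adjusted p = 0.0543, median −0.36). The 13 mitochondrial genes (median 0.27, adjusted p = 0.000619) and 19 interferon-stimulated genes (median 0.21, adjusted p = 0.0156) were called higher in cKO, each with adjusted p = 0.847 under an estimated correlation. The interferon call was lost without WT replicate 1 (adjusted p = 0.0611, median 0.13), WT replicate 2 (0.0618, median 0.20) or cKO replicate 3 (0.648, median 0.03). Quantile normalization ended the mitochondrial call (adjusted p = 0.461), and the median of these genes was 0.13 without WT replicate 1, 0.16 without cKO replicate 2, 0.41 without WT replicate 2 and 0.09 with the trend with gene length removed. Proliferation genes (23 tested, median −0.06, adjusted p = 0.317) and macrophage genes (15 tested, median 0.04 against a direction of down in camera, adjusted p = 0.868) were not called. Without WT replicate 1 or cKO replicate 2, proliferation genes were called lower in cKO (adjusted p = 0.000681 and 4.36e-07), with adjusted p = 0.767 and 0.915 under an estimated correlation. Without WT replicate 1 macrophage genes were called higher (adjusted p = 0.0363, and 0.767 with an estimated correlation). No member of these lists passed over all genes or adjusted over the list alone. Of the fat and skeletal muscle list only Actn3 was tested, at 5.02 ± 0.872 FPKM in WT and 6.14 ± 0.623 FPKM in cKO, and the 8 Y-linked genes were listed at 0 in all 6 libraries.

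**Figure D3:**
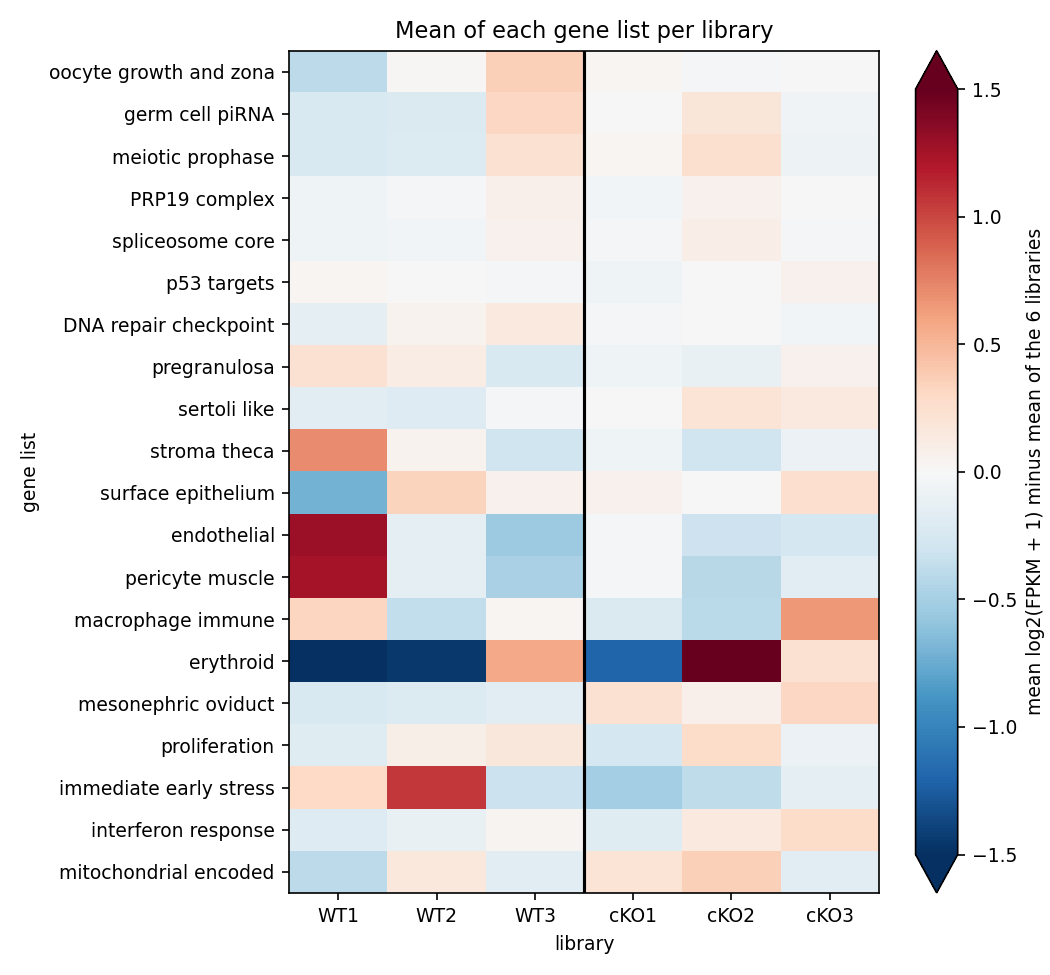
Mean log2(FPKM + 1) of the tested members of 20 gene lists in each library, as the difference from the mean of the 6 libraries, with WT to the left of the line and Bcas2 cKO to the right. The color scale ends at 1.5 on either side; WT replicate 1 stands at 1.28 for endothelial genes and cKO replicate 2 at 3.43 for erythroid genes.

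Genes of the mesonephros and oviduct epithelium were higher in cKO as a list. Of 8 tested members 0 rose and 0 fell over all genes, and 3 passed when adjusted over the list alone. By log2 fold change 6 were higher in cKO and 2 lower, among them Emx2 (−0.13), a gene chosen after its values were seen. The list mean was 2.25 ± 0.03 in WT and 2.65 ± 0.12 in cKO (SD, n = 3 each) without overlap, with an exact permutation p = 0.1, the smallest possible. Camera called the list up (adjusted p = 0.000426). With an estimated correlation, which was −0.01 and so below the preset 0.01, the adjusted p = 0.266. The median log2 fold change was 0.40, against 0.27 without WT replicate 1 and 0.07 without a filter on low values, where all listed members entered and the adjusted p was 0.00533 (0.896 with an estimated correlation). Cldn3, a tight junction protein, was at 0.850 ± 0.252 FPKM in WT and 3.39 ± 0.756 FPKM in cKO. Pax8, a transcription factor of these epithelia, was at 1.80 ± 0.610 and 3.68 ± 0.694 FPKM, and Foxj1, a regulator of motile cilia, at 0.418 ± 0.153 and 1.13 ± 0.0996 FPKM. Foxj1 reached 1 FPKM in the cKO libraries only, and Cldn3 in those and in WT replicate 3 (1.09 FPKM). Their higher level in cKO therefore also decided that they were tested. The list of Sertoli and testis-determining genes (8 tested, median log2 fold change 0.17) was also called higher (adjusted p = 0.0104, and 0.396 with an estimated correlation, here −0.06). Its list mean did not overlap between groups either, at 2.35 ± 0.09 in WT and 2.58 ± 0.10 in cKO (exact permutation p = 0.1). Non-overlapping means were thus found for 2 of the 20 lists, where chance gives 10%. By log2 fold change 6 of the Sertoli members were higher in cKO and 2 lower. Among the lower was the testis-determining gene Sox9, chosen after its values were seen. It was at 1.83, 0.875 and 1.00 FPKM in WT and at 1.44, 1.20 and 0.794 FPKM in cKO. In this list 1 member, the homeobox gene Rhox8, passed when adjusted over the list alone, at 6.004 ± 1.25 FPKM in WT and 9.98 ± 0.403 FPKM in cKO. The call of the list was lost without a filter on low values (adjusted p = 0.130, median 0.13), without WT replicate 2 (0.0745, median 0.21) or without cKO replicate 3 (0.0621, median 0.19). With the call kept, the median was 0.11 without cKO replicate 2, 0.10 with the trend with gene length removed, 0.28 with voom, 0.26 with a pseudocount of 0.1 and 0.41 at 5 FPKM.

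Fold changes also ran with gene length. Across the tested genes, which are not independent replicates, Spearman's rho between gene length and log2 fold change was −0.39. The median log2 fold change was 0.14 in the 2918 shortest genes and −0.09 in the 2918 longest. Other splits of the samples with WT replicate 1 and cKO replicate 2 on opposite sides gave rho between −0.34 and −0.27. Splits with both on the same side gave −0.09 to 0.07. The trend therefore largely followed these libraries and was not particular to genotype.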

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

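The alternatives chosen after seeing the data were voom on recovered reads, leaving out WT replicate 1 and cKO replicate 2 together, and removing the trend with gene length. The count of changed genes stayed at 0 under every alternative except 3, each of which gave 1. Array weights gave 1 lower gene, Mir6999, which had at most 4 reads in any library. Pcna-ps2, higher in cKO, was the 1 gene called both without cKO replicate 2 and without it and WT replicate 1 together, so that the leave-one-out counts ran from 0 to 1 in total and for higher genes. The cause was not tested. Bcas2 was lower in cKO under each of the 20 alternatives that gave it a value, with log2 fold changes between −0.86 (without WT replicate 1) and −1.16. Its unadjusted p stayed under 0.05 in each, and its adjusted p over all genes lay between 0.0910 (array weights) and 0.9998.

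Lists were not tested with array weights, a prior spread without a trend, protein-coding genes only or the 2-fold minimum. Among the 8 lists for oocytes, meiosis, splicing, cell death and follicle cells, the PRP19 complex, spliceosome and p53 target lists were called under none of the remaining alternatives. The meiotic call was lost with an estimated correlation (adjusted p = 0.847) and with fry (0.923), and leaving out single replicates moved its adjusted p between 1.54e-08 and 0.461. Leaving out single replicates moved the adjusted p of oocyte genes between 0.000298 (lower in cKO, without WT replicate 1) and 0.956, with a call in the other direction without WT replicate 3 (0.000577). The same fits moved germ cell genes between 6.98e-08 and 0.945, DNA repair genes between 1.97e-05 and 0.671, and pregranulosa genes between 0.00939 and 0.919. With WT replicate 1 and cKO replicate 2 both left out, oocyte genes were called lower (adjusted p = 0.000193), DNA repair genes lower (2.50e-05), and meiotic genes turned lower without a call (0.310). In that fit proliferation genes were called lower (2.60e-14), endothelial, pericyte and macrophage genes were called higher (0.000593 each), stroma genes (0.310) and surface epithelium genes (0.438) changed sign, and the erythroid (0.572, median −0.09), mitochondrial (0.211, median 0.07) and interferon calls (0.0661, median 0.13) were lost. With an estimated correlation no list had an adjusted p below 0.255 in any of these fits. Without WT replicate 1 alone, the camera direction turned for stroma (0.951), surface epithelium (0.0697), endothelial (0.0137), pericyte (0.0611), macrophage (0.0363), oocyte (0.000298), germ cell (0.796), PRP19 (0.933), spliceosome (0.933) and pregranulosa genes (0.609), although the macrophage median was above 0 in both fits. Over all leave-one-out fits the adjusted p ran from 8.36e-05 to 0.951 for stroma, 1.38e-05 to 0.418 for surface epithelium, 2.62e-06 to 0.0754 for endothelial, 0.000346 to 0.140 for pericyte and 0.0363 to 0.911 for macrophage genes. At 5 FPKM the pericyte and mesonephric lists had too few members to test. The cause was not tested. No list of the 20 was called with an estimated correlation or by fry in the fit of all samples.

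Same-numbered WT and cKO libraries had deviations from their group means that correlated at 0.22, 0.01 and −0.03, so the numbers were not taken to pair the samples. Not every library correlated best with its own number. With a replicate block the count of changed genes was 0, Bcas2 had a log2 fold change of −1.05, and adjusted camera p-values were 0.774 for oocyte and 0.00364 for meiotic genes. Of 101 single genes examined, 19 changed sign under at least 1 alternative and 82 under none. Depth limits short genes near 1 FPKM.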

Other observations

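The tests for fewer oocytes, for a high WT value of Bcas2 and for a lower share of germ cells in WT replicate 1 were chosen only after the result was seen. Of further genes chosen after their values were seen, Pcna-ps2 was at 0.319, 0.412 and 0.773 FPKM in WT and at 19.2, 1.18 and 16.6 FPKM in cKO, and its reads can be shared with those of Pcna. Reg2 was listed at 0 in WT and at 2.74, 1.71 and 1.01 FPKM in cKO. Pcna-ps2 and Reg2 reached 1 FPKM in cKO libraries only, so their higher level there also decided that they were tested. Wfdc2, an epithelial secreted protein, was at 0.322, 2.10 and 0.862 FPKM in WT and at 7.99, 1.92 and 6.51 FPKM in cKO. All 3 had an adjusted p of 0.955 in limma. A list of 20 motile cilia genes, 8 of them tested, had a mean log2 fold change of 0.13, with overlapping groups.

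Bcas2 was lower in all 3 cKO ovaries. If a smaller number of oocytes were the source, oocyte, germ cell and meiotic genes would fall by at least about as much, since other cells can also express Bcas2. The 103 tested members of those lists had a median log2 fold change of 0.0896 (SD 0.21 across genes), against −1.05 for Bcas2, and 0 of them lay at or below it. Without WT replicate 1, which was low in oocyte genes, the medians were −0.14 for oocyte, −0.05 for germ cell and 0.05 for meiotic genes. These values argue against an oocyte loss large enough to give the drop in Bcas2, while a smaller loss stays open. The high value of WT replicate 1 does not account for the difference either, since without it the log2 fold change was −0.86 (SE 0.11). Loss of Bcas2 transcript from oocytes that are still present stays as the hypothesis the design names. It was not tested, since Bcas2 in oocytes was not measured apart from that in other cells.

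WT replicate 1 stood apart with higher vessel and stroma genes. More vessel tissue in that sample is a candidate explanation. A second list of endothelial genes, 15 of them tested, had a mean in that library 0.97 above the next library. Genes of the same cell type move together across libraries, with an estimated correlation of 0.92 in the first endothelial list. The second list therefore shows that the pattern reaches other endothelial genes, but does not test its source. A lower share of germ cells would raise the markers of every somatic cell type alike, but surface epithelium genes lay below every other library, at −0.71 against the lowest of them. Oocyte genes were also at −0.38 against the lowest other library. Germ cell and meiotic genes lay at −0.23 each from the mean over all libraries, but WT replicate 2 was at −0.21 for both. Germ cell and meiotic genes therefore did not set WT replicate 1 apart. Whether it held fewer germ cells beside a change among somatic tissues stays open. Whether the sample held more tissue of the ovarian medulla or hilum, or differed in dissection, was not tested.

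The list mean of mesonephric and oviduct epithelial genes was higher in all 3 cKO ovaries than in any WT ovary, although no member passed over all genes and 2 of 8 were lower. Among 20 lists, 2 had non-overlapping means, this list and the Sertoli list, where chance gives 10%. Cldn3 alone is not the source: without it the mean log2 fold change was 0.29 and the groups stayed apart. The members left include Foxj1, which was tested only because of its level in cKO, so the filter may have added to that separation. With all listed members entered, the median log2 fold change was 0.07. Oviduct or mesonephric epithelium left on the cKO ovaries is a candidate explanation. A second list of epithelial genes, 20 of them tested, had a mean log2 fold change of 0.31. Its groups overlapped (exact permutation p = 0.2). Part of that difference came from WT replicate 1. Relative to the mean over all libraries, that library lay at −0.41, against −0.10 and 0.05 in WT replicates 2 and 3. Most abundant in the first list were Epcam and Emx2, named after their values were seen, which the ovarian surface epithelium also expresses, and Epcam is not a marker of the oviduct alone. More tissue and a change within the ovary cannot be told apart here, because the second list neither separated the groups nor moved the other way.

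Since Bcas2 acts in splicing, introns left in RNA were looked for in snoRNA and miRNA genes, many of which lie in introns. Their share of reads differed by 0.000255 percentage points between cKO and WT, and the groups overlapped, so this measure did not separate the groups. Across protein-coding genes, rho between the number of introns and the log2 fold change was −0.30, and the highest value among the other 9 splits of the samples was 0.28 in size. With 10 splits no share under 0.05 is possible. Once gene length was taken out, the partial rho was −0.11, between the limits set for a trend of length alone and for one of introns, and the partial rho of length given introns was −0.34. The relation therefore went more with length than with introns. Without gene length taken out, other splits with WT replicate 1 and cKO replicate 2 on opposite sides gave an intron rho between −0.28 and −0.12. Splits with both on the same side gave −0.08 to 0.06. The intron relation thus largely followed these libraries, and whether any part for introns goes with genotype stays open. Across all tested genes, a set that also holds other biotypes, the relation with gene length alone was −0.39, and 0.34 in size in the highest of the other splits. Single libraries ran both ways, from −0.40 in cKO replicate 2 to 0.31 in WT replicate 1, and the rest lay between −0.14 and 0.11.

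The real split gave 0 genes past the threshold and the highest other split gave 1. Since 0 is the lowest possible count, each of the 10 splits gives at least as many by construction, and 10 splits cannot give a share under 0.05.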
